A study of Homo sapiens with 5 samples.

How the data were processed

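Expression was measured in HK-2 cells, an established line of human renal proximal tubular epithelial cells, with a nylon membrane cDNA array per culture condition. Per the labels, the RNA was labelled radioactively and prepared after the manual of the Atlas nylon cDNA arrays. The series title describes the measured genes as stress-related. A table of 243 spots on 5 arrays was analysed, and each of the 5 conditions had 1 array. With 1 array per group there is no estimate of the spread between cultures or between hybridizations, and no significance test was made.

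The deposited values are intensities on a linear scale, whole numbers from 118 to 90664. Background correction, image software and scaling are not given in the sources used here. The values show that the authors' intensities had been scaled per array: the array sums differed by 1.85% at most, and between 98.4% and 100% of the values of an array were whole multiples, rounded down, of a single step. That step was 2 for the control, 3.19 for GF/FAF HSA, 2.43 for GF HSA, 2.85 for AngII and 2.36 for AngII with candesartan. The array medians still differed by 1.71-fold. A rule set before the data were examined kept the deposited scale only if the medians lay within 1.25-fold, so each array was multiplied by 1 factor that set the median log2 ratio to control over the 243 spots to 0. The factors were 1.36 for GF/FAF HSA, 1.15 for GF HSA, 1.40 for AngII and 1.07 for AngII with candesartan. The shifts they removed were -0.44, -0.20, -0.49 and -0.10 on the log2 scale, so every change below is relative to the median spot. All values were above 0 and all 243 spots were treated as measured. The precision is limited by the number of arrays.

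The spots carry array codes, and neither the values nor the gene table used here pairs them with genes. Of the 168 codes with a letter, 0 matched a gene symbol or locus tag, and 33 were spelled like a gene synonym. Of the 75 codes made of digits, 61 were equal to a gene identifier number. Whether these matches are coincidence was not tested, and they were not used. Spots are therefore reported by code, and for this reason the 15 gene lists that had been fixed in advance (heat shock proteins and chaperones, the CCT chaperonin complex, antioxidant enzymes, metallothioneins, glutathione transferases and glutathione synthesis, phase I enzymes, phase II enzymes, drug transporters, DNA repair, cell cycle, stress kinases, apoptosis, inflammation, housekeeping genes and markers of other kidney cells) gave no result. Scaling on housekeeping genes was likewise not run.

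For each of 6 comparisons the log2 ratio per spot was taken, and spots at a ratio of 2 or more in either direction were counted. Spots were named by a rule set in advance: the 10 largest ratios per direction among those at 2-fold or more whose brighter value was at or above 8124, the median of all scaled values. Because the codes name no gene, the text gives the 2 largest per direction. The rule also listed 15 genes by symbol, which could not be located. Ratios that share an array are related by chance. Counts over such ratios were therefore set beside the mean and central 95% range of the same count when the values of each spot were permuted among the arrays involved, 10000 times, and overlaps also beside the size expected of independent lists. The share of AngII spots that returned with candesartan was compared with its permuted share, since the number of AngII spots also varies in permuted values. These ranges were computed under the alternative settings too, after the data were seen. Permuted counts of shared spots are not given for the deposited scale, whose shift of whole arrays permutation removes. Permuted shares of returning spots are given for that scale and carry the same limit. So do all permuted ranges after background subtraction, which left more lower than higher spots against control on every treated array. These ranges describe exchangeable arrays and are not tests of the treatments. The alternatives were the values as deposited, quantile normalization, a filter on dim spots, and an offset of 5352 (the 25th percentile of scaled values) added before taking logs. After the data were seen, the removal of spots within 5% of an array's highest value was added. So was the subtraction of each array's 5th percentile with a filter on dim spots. In simulated data for AngII against control (243 spots, 60 of them changed 4-fold, noise of 0.3 on the log2 scale), 98.3% of the changed spots and 4 unchanged spots passed 2-fold. The noise was assumed per array and not estimated, and no trend with brightness was simulated. Log2 ratios between the real arrays had SDs of 0.62 to 0.94, any treatment changes included. The simulation thus checks the calculation and gives no rate of false calls for these arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.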

Results

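HK-2 cells were kept without serum for 48 h and then cultured for 24 h under 5 conditions, each measured on 1 array of 243 spots. The control received fresh medium alone. Albumin, the main protein of plasma, was given at 30 mg/ml as human serum albumin (HSA) from 2 preparations, labelled GF/FAF and GF. Angiotensin II (AngII), the effector peptide of the renin-angiotensin system, was given at 1 uM. In the last condition AngII at 1 uM was combined with candesartan at 0.1 uM, which had also been present for 1 h beforehand; candesartan blocks an angiotensin receptor. The comparisons ask how stress-related transcripts of proximal tubular cells respond to albumin and to AngII, and whether candesartan alters the AngII profile. The spots are known here by array code only, so no gene or pathway is named.

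Summed intensities ranged from 2998457 on the AngII array to 3054073 on the AngII with candesartan array. Median intensities were 9184 for the control, 5369 for GF/FAF HSA, 6632 for GF HSA, 5590 for AngII and 7682 for AngII with candesartan. The 10 brightest spots carried 19.1% of the summed intensity on the control array, 27.9% with GF/FAF HSA, 22.4% with GF HSA, 27.4% with AngII and 22.1% with AngII and candesartan. Between 4 and 7 spots per array lay within 5% of the highest value, where a difference can be understated. A ratio there can also come from the array scales. Spot 903 held the highest value on the control and AngII arrays (64512 and 88537) and had a log2 ratio of 0.94. For 9 of the 24 ratios given for single spots, the dimmer value lay at or below the 5th percentile of its array: S145 and 727 with GF/FAF HSA, 704 with GF HSA, S8 between the albumins, S145 with AngII, S125 and S74 with candesartan against control, and S128 and S58 with candesartan against AngII. Their folds and ranks are approximate, and are lower bounds if such values are mostly background. Spots S158, S34 and S126, also given below, rest on values under the 5th percentile too. These were 118 (S158) and 392 (S34) with GF/FAF HSA, 1195 (S34) with AngII and 242 (S126) with AngII and candesartan. Whether such values are failed spots was not tested. No condition was replicated, so the values below carry no error and the differences compare single arrays.

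With GF/FAF HSA, 19 of 243 spots were at least 2-fold higher and 24 at least 2-fold lower than in the control, and 200 lay within 2-fold. Bright spots here are those whose brighter scaled value in a comparison was at or above 8124. The largest increases among them were at S47 (3.22-fold, deposited intensity 17072 in the control and 40472 with albumin) and 763 (3.20-fold, 10538 and 24806). The largest decreases among bright spots were at S145 (5.91-fold lower, 9520 and 1186) and 727 (5.75-fold lower, 8674 and 1110). The dimmer spots S158 and S34 fell further, with log2 ratios of -4.97 and -2.82. After quantile normalization the log2 ratios of S145 and 727 were -1.91 and -1.86, in place of -2.56 and -2.52. An offset of 5352 added before taking logs gave -1.09 for S145 and -1.03 for 727. Among the 61 spots that were brightest on the 3 other arrays, 17 were 2-fold higher and 0 lower. Among the 61 dimmest, 1 was higher and 16 were lower. On the deposited scale, the split was 4 higher and 46 lower, and with the offset it was 11 higher and 3 lower.

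With GF HSA, 24 spots were at least 2-fold higher and 31 at least 2-fold lower than in the control. The largest increases among bright spots were at 651 (4.46-fold, from 9590 to 37283) and S127 (3.75-fold, from 4316 to 14117). Neither spot passed 2-fold on any other treated array. The largest decreases among bright spots were at 904 (8.86-fold lower, from 38460 to 3786) and 704 (7.86-fold lower, from 10924 to 1212). With the offset the log2 ratios were 1.16 at S127, -2.18 at 904 and -1.27 at 704, in place of 1.91, -3.15 and -2.97. After subtraction of each array's 5th percentile they were 5.49 at S127 and -5.24 at 904. On the other treated arrays spot 904 had log2 ratios to control of -0.44 (GF/FAF HSA), -0.97 (AngII) and -0.51 (AngII with candesartan), and spot 704 of -0.61, -1.34 and -0.65. On the deposited scale the AngII values were 2.75-fold lower than control at 904 and 3.54-fold lower at 704, and the GF/FAF HSA value at 704 was 2.07-fold lower. Of the 61 brightest spots 13 were higher and 2 lower, and of the 61 dimmest 5 were higher and 11 lower. The deposited scale gave 13 higher and 41 lower, and the offset 9 higher and 7 lower.

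The albumin preparations were also compared directly, at the same concentration. With GF HSA, 19 spots were at least 2-fold higher and 21 at least 2-fold lower than with GF/FAF HSA. The ratio fell with brightness across spots (Spearman rho -0.37). Of the 61 brightest spots 1 was higher and 6 lower, and of the 61 dimmest 11 were higher and 3 lower. Among bright spots, the largest differences upward were at S127 (3.83-fold) and S8 (3.67-fold, 1764 with GF/FAF and 7665 with GF). The dimmer spots S158 and S34 had larger log2 ratios, 5.06 and 3.09. The largest downward among bright spots were at 904 (6.53-fold lower) and 791 (6.31-fold lower, 17159 with GF/FAF and 3220 with GF). Against control, 6 spots were 2-fold higher and 12 spots 2-fold lower with both preparations, and 0 moved 2-fold in opposite directions. Independent lists of these sizes would share 1.88 and 3.06 spots. Because both ratios use the same control array, permuted values gave 8.35 (4 to 13) and 7.65 (3 to 12), so the higher overlap lay within the range that the shared control gives and the lower one on its upper bound. Without spots near the ceiling, 12 lower spots were shared against a range of 3 to 11. The following settings did not pass their ranges: 11 (3 to 11) with the filter on dim spots, 9 (3 to 10) after quantile normalization and 1 (0 to 4) with the offset. On the deposited scale, where the arrays are shifted as a whole, 1 of 4 and 13 higher spots and 21 of 46 and 41 lower spots were shared, against 0.21 and 7.76 for independent lists. After background subtraction 3 higher and 20 lower spots of 133 were shared, against 0.66 and 9.26 for independent lists. The permuted ranges were 5 to 16 and 4 to 13, so the higher overlap lay below its range and the lower one above. The lists there held 8 and 11 higher but 28 and 44 lower spots. Permutation does not keep that imbalance, so these positions cannot be judged. As deposited, 34 spots were higher and 16 lower with GF HSA than with GF/FAF HSA, and with the offset 2 were higher and 8 lower. With the offset the log2 ratio at S8 fell below 2-fold (0.87), and those of S127, 904 and 791 were 1.17, -1.80 and -1.66. Background subtraction gave 3.60, -4.24 and -4.99 for S127, 904 and 791.

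With AngII, 21 spots were at least 2-fold higher and 21 at least 2-fold lower than in the control. Among bright spots, the largest increases were at S47 (3.86-fold, from 17072 to 47010) and 763 (3.82-fold, from 10538 to 28709). The largest decreases among bright spots were at S145 (5.78-fold lower, from 9520 to 1175) and 907 (4.27-fold lower, from 16352 to 2735). S47, 763 and S145 were also among the largest differences with GF/FAF HSA, and 907 had a log2 ratio of -2.16 there. With GF HSA the log2 ratios were 1.75 at S47, 0.28 at 763, -1.16 at S145 and -2.40 at 907. Quantile normalization changed the AngII log2 ratio of S47 from 1.95 to 1.09 and that of S145 from -2.53 to -3.56. With the offset S145 was at -1.09 and 907 at -1.24, and after background subtraction 907 was at -4.25. Of the 61 brightest spots 19 were higher and 0 lower, and of the 61 dimmest 0 were higher and 17 lower. The deposited scale gave 5 higher and 66 lower, and the offset 14 higher and 3 lower.

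**Figure D1:**
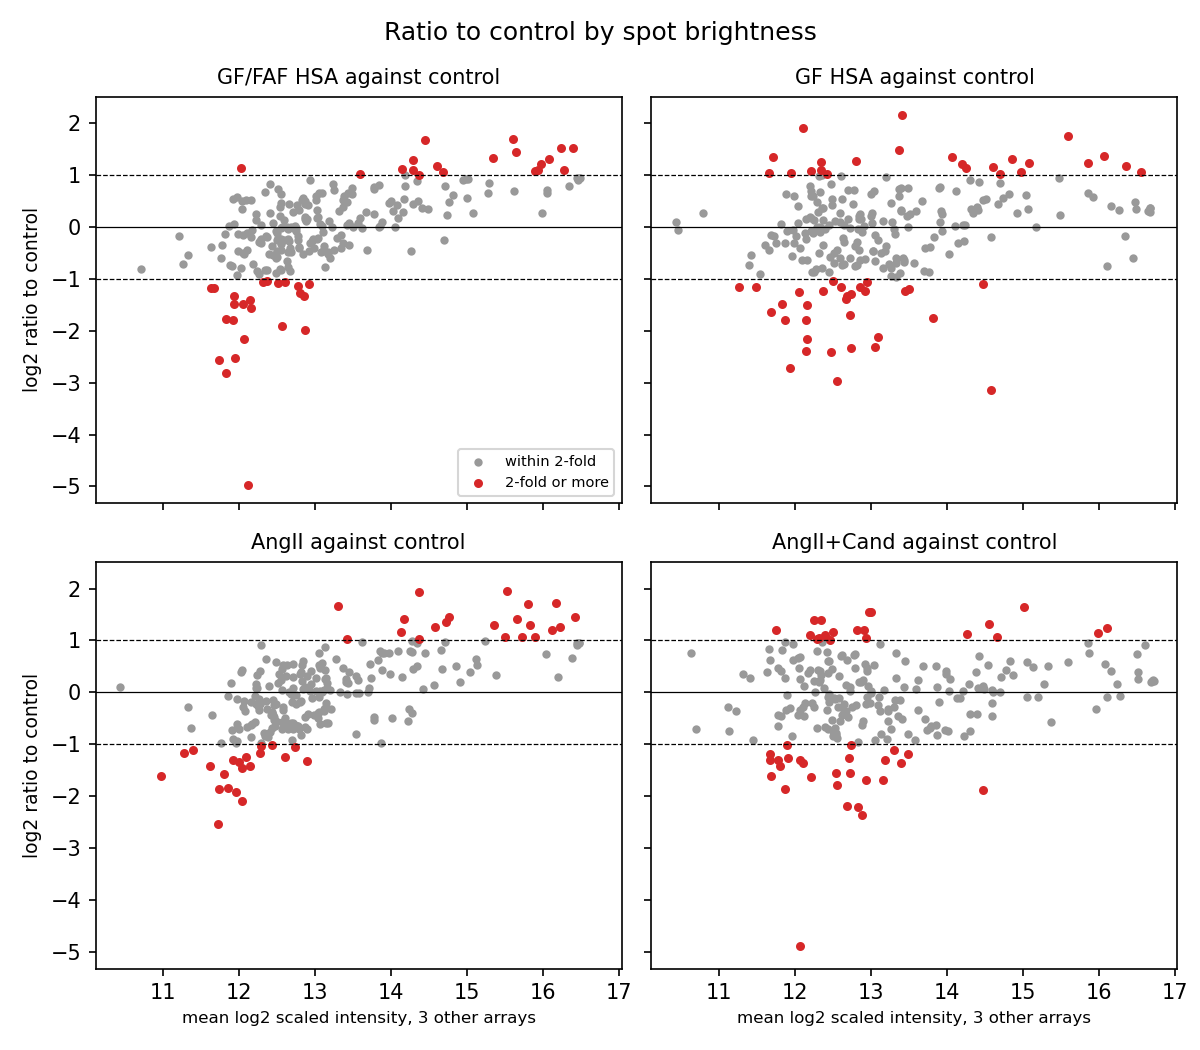
Log2 ratio to control (y axis) against the mean log2 scaled intensity on the 3 other arrays (x axis), 1 point per spot and 1 panel per treated array; red points differ 2-fold or more and dashed lines mark 2-fold. With GF/FAF HSA and with AngII the ratio climbs with brightness across the spots (Spearman rho 0.65 and 0.68), and less so with GF HSA (0.28) and AngII with candesartan (0.12).

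The AngII and GF/FAF HSA profiles shared 12 spots at least 2-fold higher and 10 at least 2-fold lower than control. Independent lists would share 1.64 and 2.07, and permuted values with the shared control gave 6.32 (2 to 10) and 3.65 (1 to 7), so both overlaps lay above the range. This held in both directions only under some settings. As deposited, 3 higher and 33 lower spots were shared, against 0.08 and 12.5 for independent lists. Quantile normalization gave 7 (1 to 8) and 8 (1 to 6), and the offset 9 (0 to 6) and 2 (0 to 3). Background subtraction gave 6 (2 to 10) and 20 (3 to 11) over 138 spots, against 0.66 and 7.14 for independent lists. Part of each overlap may come from the shared control array. Neither reference allows for the trend with brightness that both arrays show. Of the 61 brightest spots, 17 were higher with GF/FAF HSA and 19 with AngII. Of the 61 dimmest, 16 and 17 were lower. How much of the overlap the trend gives was not tested. AngII and GF HSA shared 9 higher and 9 lower spots, against 2.07 and 2.68 for independent lists and 10.7 (6 to 16) and 7.35 (3 to 12) for permuted values. As deposited, they shared 2 higher and 22 lower, against 0.27 and 11.1 for independent lists. After background subtraction they shared 5 higher and 17 lower of 134 spots. The permuted ranges were 7 to 18 and 3 to 12, so the first lay below its range and the second above. The lists held 15 and 11 higher but 24 and 43 lower spots, an imbalance that permutation does not keep. Independent lists would share 1.23 and 7.70. Compared directly, without the control, the AngII and GF/FAF HSA arrays differed 2-fold at 12 spots. The other 9 pairs of arrays differed at 40 to 62 spots.

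**Figure D2:**
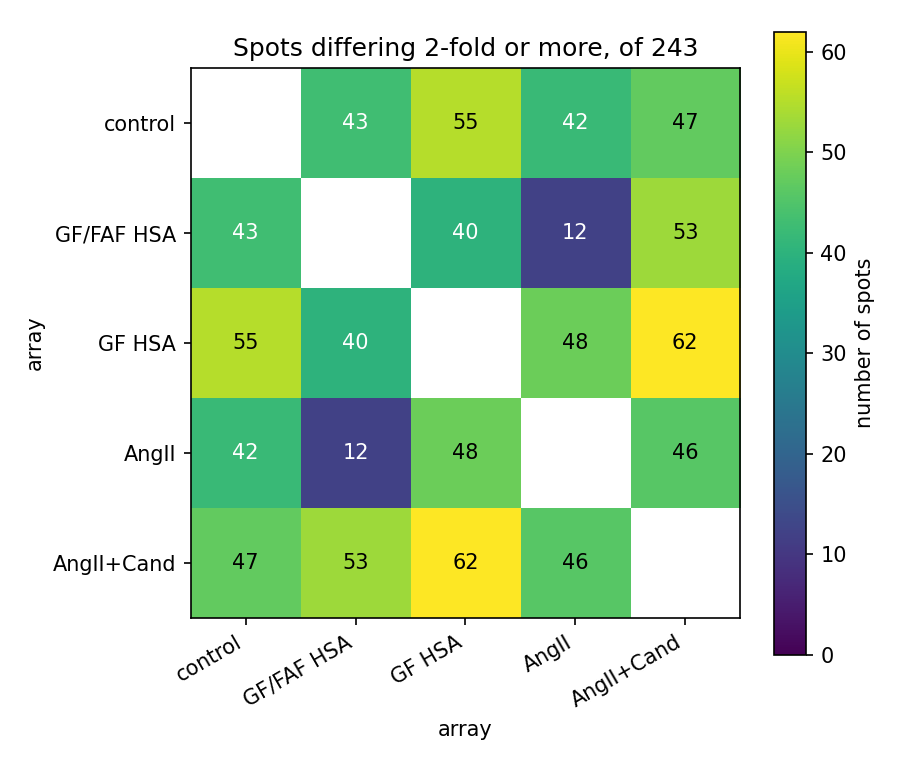
Number of spots (colour and printed value) that differ 2-fold or more between each pair of the 5 arrays, of 243 spots after median scaling; both axes list the arrays. AngII and GF/FAF HSA differ at 12 spots, and the remaining pairs at 40 to 62.

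With AngII and candesartan, 20 spots were at least 2-fold higher and 27 at least 2-fold lower than in the control. Of the 61 brightest spots 6 were higher and 1 lower, and of the 61 dimmest 5 were higher and 12 lower. The largest increases among bright spots were at S33 (3.13-fold, from 20682 to 60335) and S23 (2.92-fold, from 6610 to 18022). The largest decreases among bright spots were at S125 (5.11-fold lower, from 8568 to 1564) and S74 (4.61-fold lower, from 12850 to 2603). The dimmer spot S126 fell further (log2 ratio -4.88, from 7624 to 242). With AngII alone S33, S23, S125 and S74 had log2 ratios to control of 0.98, 0.19, -1.01 and -0.85. The deposited scale gave 15 higher and 32 lower, and quantile normalization 31 higher and 27 lower. With the offset, the log2 ratio of S125 was -0.99, just within 2-fold, and that of S74 was -1.16. Background subtraction gave 2.42 for S23.

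Relative to AngII alone, 22 spots were at least 2-fold higher and 24 at least 2-fold lower with candesartan. The ratio fell with brightness across spots (Spearman rho -0.58). Of the 61 brightest spots 0 were higher and 8 lower, and of the 61 dimmest 12 were higher and 1 lower. Among bright spots, the largest differences upward were at S128 (3.69-fold, 1619 without and 7811 with candesartan) and S142 (3.38-fold, 2849 and 12583). The largest downward among bright spots were at S58 (6.08-fold lower, 12211 and 2625) and C171 (3.86-fold lower, 8801 and 2980). Dimmer spots moved further in each direction: the log2 ratio was 1.92 at S34 and -3.26 at S126. The deposited scale gave 47 higher and 9 lower, and the offset 1 higher and 9 lower. With the offset, S128 fell below 2-fold (log2 ratio 0.85), and S142, S58 and C171 were at 1.01, -1.46 and -1.05. Background subtraction gave 3.51 for S142 and -4.52 for C171.

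Of the 21 spots that were 2-fold higher with AngII, 16 were no longer 2-fold above control with candesartan, and the median log2 ratio of the 21 to control was 0.58 in place of 1.30. Of the 21 that were 2-fold lower with AngII, 11 were no longer 2-fold below control, and the median of the 21 was -0.85 in place of -1.34. Spots picked for a high or low AngII value return towards control by selection alone: the share that returned was 76.2% and 52.4%, and permuted values gave 67.2% (50% to 83.3%) and 65.7% (47.8% to 82.4%). A move of at least 2-fold against the AngII change occurred at 7 of the higher spots and 5 of the lower ones, where permuted values gave 7.65 (3 to 12) and 7.32 (3 to 12). Both the returning shares and these counts were thus within the range of exchangeable arrays in both directions after median scaling. Quantile normalization turned the majority into a minority: 4 of 15 higher spots returned (26.7%, permuted 40.9% to 77.3%) and 7 of 18 lower ones (38.9%, permuted 43.8% to 80%), below both ranges. After background subtraction 10 of 26 lower spots returned (38.5%, permuted 47.8% to 84.6%), also below. As deposited, 4 of 5 higher and 46 of 66 lower spots returned, and with the offset 12 of 14 and 3 of 3. The permuted share was 66.6% for lower spots as deposited and 88.3% for higher spots with the offset, against 69.7% and 85.7% observed. For higher spots as deposited the observed share was 80% (4 of 5). The permuted range was 45.2% to 75.9%, from lists of 29.0 spots on average. A list of 5 spots cannot be judged against that range. Permutation also removes the shift of whole arrays on that scale, for higher and lower spots alike. S145 and 763, both named for AngII, had log2 ratios to control of -2.53 and 1.93 with AngII and of -0.75 and 1.06 with candesartan.

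**Figure D3:**
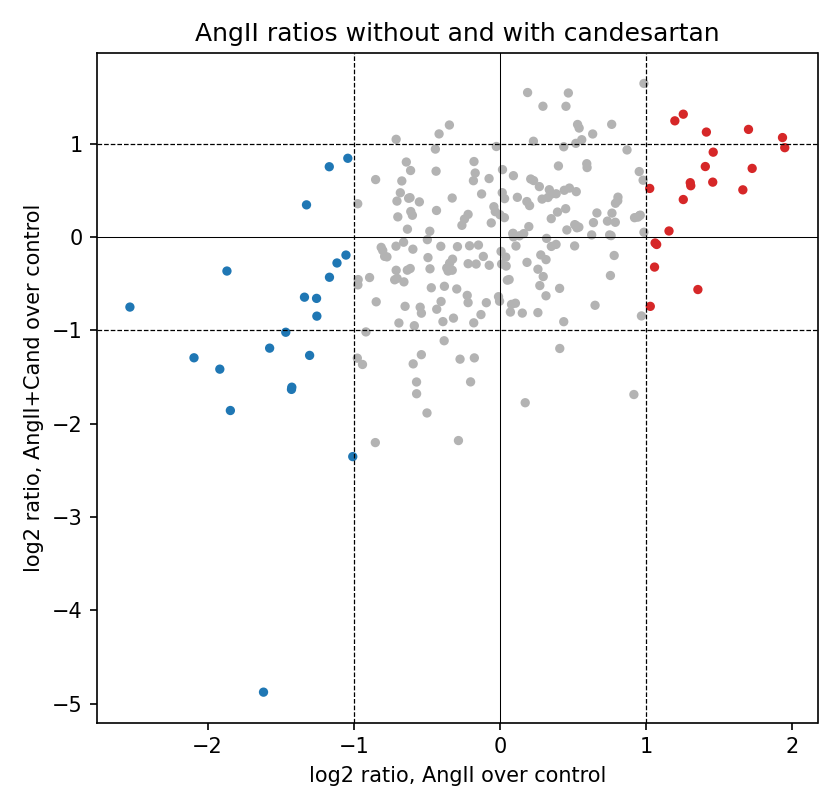
Log2 ratio to control with AngII and candesartan (y axis) against that with AngII alone (x axis), 1 point per spot; red and blue points are the 21 spots at least 2-fold higher and the 21 at least 2-fold lower with AngII, and dashed lines mark 2-fold. Of the red points 16 lie below the upper dashed line and of the blue points 11 lie above the lower one.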

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

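The scale set the balance of higher and lower spots. The 24 single-spot ratios named in the report kept their sign under every alternative that could be computed for them. Only quantile normalization and background subtraction could have reversed a sign. The dim-spot filter and the removal of spots near the ceiling leave a ratio unchanged, and the offset keeps its sign. The deposited scale shifts ratios by at most 0.49, less than any of these ratios. With the offset 17 of the 24 moved by 0.58 or more on the log2 scale and 21 stayed past 2-fold; S8 (0.87), S125 (-0.99) and S128 (0.85) did not. Quantile normalization moved 4 of the 24 (S145 and 727 with GF/FAF HSA, S47 and S145 with AngII, values in the report), and background subtraction 9 of the 15 whose values all lay above the 5th percentile. Where counts moved, the cause was not tested except where the alternative's own construction shows it. In the lists that follow, counts are higher then lower, and the main counts stand in the report. As deposited, GF/FAF HSA against control gave 4 and 46, GF HSA 13 higher, GF HSA against GF/FAF HSA 34 higher, AngII 5 and 66, and candesartan against AngII 47 and 9. As deposited, 4 of 5 higher and 46 of 66 lower AngII spots returned within 2-fold of control with candesartan. The shared spots were then 1 and 21 for both albumins, 3 and 33 for AngII with GF/FAF HSA, and 2 and 22 for AngII with GF HSA. Quantile normalization gave 10 higher for GF/FAF HSA and 31 higher for AngII with candesartan against control, 4 of 15 and 7 of 18 returning spots, and 7 higher spots shared by AngII and GF/FAF HSA. Without dim spots, GF HSA against GF/FAF HSA had 10 higher, AngII against control 12 lower and candesartan against AngII 14 higher, each over spots bright on either of the arrays compared. Over the 177 spots bright on any of the control, AngII and candesartan arrays, 7 of 14 AngII-lower spots returned. The offset shrinks ratios of dim spots by construction. It left 11 and 3 for GF/FAF HSA, 9 and 7 for GF HSA, 2 and 8 between the albumins, 3 lower for AngII, 4 and 4 for AngII with candesartan against control, and 1 and 9 against AngII. With the offset 3 of 3 AngII-lower spots returned, and the shared spots were 3 and 1 for the albumins, 2 lower for AngII with GF/FAF HSA, and 4 and 1 for AngII with GF HSA. With each array's 5th percentile subtracted (chosen after seeing the data), GF/FAF HSA had 8 higher and AngII with candesartan 31 higher than control, and 9 of 15 AngII-higher spots returned. The shared spots were 3 and 20 for the albumins, 6 and 20 for AngII with GF/FAF HSA, and 5 and 17 for AngII with GF HSA. Leaving out spots near the ceiling (also chosen after seeing the data) moved 0 of the 20 counts by over 1.5 times. No paired analysis was possible because each group has 1 array. No replicate could be left out, and housekeeping scaling and the gene lists were not run because the codes name no genes.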

Other observations

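After median scaling, spots 491 and S160 were at least 2-fold higher than control on all 4 treated arrays. Their log2 ratios ran from 1.16 to 1.31 and from 1.20 to 1.36. A further 4 spots were at least 2-fold lower on all 4, among them 907 (log2 ratios from -2.40 to -1.30) and S114 (from -1.92 to -1.42). Permuting the 5 values of each spot gave 3.61 spots higher (1 to 7) and 2.01 lower (0 to 5), so these numbers lay within the range of exchangeable arrays. They depend on the scale: as deposited, 0 spots were higher and 8 lower on all 4 arrays, and with the offset 1 was higher and 0 lower. Background subtraction gave 7 lower, above its permuted range of 0 to 5, which does not keep the excess of lower spots in that setting. As deposited, 491 passed 2-fold on the candesartan array only, and S160 on the GF HSA and candesartan arrays. After quantile normalization 491 passed on all 4 (1.02 to 1.62) and S160 on none (0.05 to 0.79). An unusual value on the single control array produces the same picture as a response common to all treatments. Among the dimmer spots, chosen after their values were seen, S158 had an intensity of 118 with GF/FAF HSA against 5008 in the control, and S126 had 242 with AngII and candesartan against 7624.

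The patterns below were noticed first. The tests of their explanations were written down before the tests were run. Their bootstrap intervals resample spots within the same single arrays, so they hold no spread between cultures or hybridizations. Brighter spots stood higher against control on the AngII and GF/FAF HSA arrays. One candidate explanation is an additive background that differs between the arrays. Subtracting each array's 5th percentile lowered the Spearman correlation of ratio with brightness across 219 spots from 0.70 to 0.48 for AngII (bootstrap 95% interval 0.37 to 0.59) and from 0.69 to 0.45 for GF/FAF HSA (0.32 to 0.56). The criterion set in advance was on the intervals: one wholly below 0.2 for a full explanation, and one wholly above 0.4 against it. Both intervals include 0.4 and lie above 0.2, so neither criterion was met and background stays open. A response of strongly expressed genes to treatment also stays open and was not tested, since each condition has 1 array.

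As deposited, the median ratio to control was below 0 on every treated array. A candidate explanation is a scaling to equal sums in which a few bright spots weigh heavily. With sums made equal without the 20 brightest spots, the median log2 ratio moved from -0.49 to -0.12 for AngII (-0.29 to -0.03) and from -0.44 to -0.11 for GF/FAF HSA (-0.22 to 0.01). The intervals reached past the 0.1 set in advance, so the criterion was not met. The smaller shift is no support for scaling either. Equalizing the sums of the remaining spots draws their median ratio towards 0 whatever raised the share of the bright spots. Whether the excess of lower spots on the deposited scale reflects scaling stays open.

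The closeness of the AngII and GF/FAF HSA arrays did not depend on the control. Their log2 ratios had an SD across spots of 0.62, against 0.77 to 0.94 for the other 9 pairs. A brightness distribution common to these arrays was tested by quantile normalization, which gives all arrays the same distribution. The pair remained the closest: its SD was 0.17 below that of the next pair (bootstrap 95% interval over spots 0.05 to 0.24). For these single arrays this argues against that explanation. Hybridization or processing of these arrays together, which the labels do not record, and a like response of the cells to AngII and this albumin preparation may each account for the pattern and were not tested.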
